A study of Mus musculus with 8 samples.

How the data were processed

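The data are strand-specific DNA:RNA immunoprecipitation sequencing of mouse haematopoietic stem cells, with 2 immunoprecipitated and 2 input libraries for each of 2 ages, 8 samples in all. Groups and replicate numbers were taken from the sample labels. Per the submitters' processing notes the genome build was GRCm38, and the tools were Trim Galore, Bowtie2 2.4.4, MACS3 3.0.0b1 and deepTools 3.5.1. The order of these steps, their settings, the treatment of duplicate and multiply mapping reads, and the way replicates and inputs were combined are not given in the sources used here. The 4 deposited peak lists hold 1 age and 1 strand each. The word normalized in the peak names is not explained by the labels, and neither is which strand the forward list stands for.

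Each deposited line gives a peak, its summit, the ratio of immunoprecipitated signal over the local background (the fold enrichment of the authors' peak caller), and the −log10 p-value and −log10 q-value that the authors' caller gave it. The lowest −log10 q-values of the 4 deposited lists lay between 1.32 and 1.34. These per-peak values were used to rank, filter and describe peaks, with the same cut-offs set on the lists of both ages. They also served to recover reads, and to thin or match peaks between the ages.

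The reads at each summit and the background were recovered from the deposited fold and −log10 p-value. In the form MACS uses, the fold is the pileup plus 1 over the background plus 1, and p is the upper tail of a Poisson distribution with that background. Solved for a whole number of reads, both equations matched the deposited −log10 p within 0.1% for 100% of the peaks of each list. On simulated data 100% of 4000 pileups came back exactly, and of 2779 pileups scaled by 0.8 to broken numbers 9.68% matched as whole reads. If reads were thinned before calling, the numbers are reads after thinning. This step was chosen after the data were seen. The recovered genome background, 0.824 in young and 0.689 in aged, stands in for depth, since the files give no read totals. Intervals on shares are 95% Wilson intervals, and they cover counting error only.

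Peaks of different lists were called shared when they overlapped by at least 1 bp on the same strand. Random expectation came from 1000 placements of the same peaks on their own chromosomes, within the span that peaks cover. The alternative gene-end settings and the closing test of weak young peaks used 100 placements. In a simulated aged forward list with 12.0% of 8088 peaks planted as shared, 12.5% were found as shared, the excess being chance overlap. Gene positions came from the RefSeq table of assembly GRCm38.p6 given for the series, with 34614 protein-coding and lncRNA genes (21887 and 12727). A summit was placed within 1 kb of either gene bound, in a gene interior, or outside genes. The design written before the data were examined also named promoter, UTR, exon and intron classes, the strand of a peak against the strand of its gene, and base composition. The table holds no gene strand, transcript, exon or sequence, so promoters were replaced by gene ends and the other parts were not run. A gene carried a peak when a summit of either strand lay in its body extended by 1 kb. Random gene counts came from 200 placements. Of the 18 gene lists, 16 were written out and 2 (ribosomal protein and histone genes) were set by symbol, all before the data were examined. Each list was set beside 10000 random lists matched on biotype and length decile, with the percentile taken at the middle of ties. In 100 simulated lists with no effect, 3 fell outside the central 95%.

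Genes were named by a rule set before the data were examined. It takes the 10 genes with the highest fold per age, the 10 strongest genes found in 1 age only, and from each list up to 4 members with the strongest peak and up to 4 found in 1 age only. Predicted genes without a standard symbol were skipped, and some genes that the rule selects are not reported here. Genes named without a value, and the 3 ribosomal protein genes found in young only, fall outside the rule and were added after their values were seen to complete a count.

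No test between ages was run, since each age has 1 combined list per strand and the libraries themselves were not used. Alternatives set beforehand were a −log10 q of at least 5, a fold of at least 5, merging within 500 bp, autosomes only, a reciprocal overlap of 50%, peaks extended by 1 kb, lists cut to the strongest 8088 peaks by −log10 p, overlap with either strand, shifts of 10 to 100 kb as random placement, gene-end windows of 500 bp and 3 kb, and protein-coding genes only. Alternatives added after seeing the data were a −log10 q of at least 10, a fold of at least 10, at least 20 reads, peaks at the genome background, and peaks with no peak of the other strand within 1 kb. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.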

Results

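The series compared R-loops in young and aged haematopoietic stem cells, the rare bone marrow cells that renew all blood lineages. The cells were taken from mouse bone marrow as lineage-negative, cKit-positive, Sca1-positive and CD34-negative cells. R-loops are DNA:RNA hybrids that form when a transcript stays paired with its template strand. They were captured with the S9.6 antibody and sequenced with a protocol that keeps the 2 strands apart (ssDRIP-seq). The 8 samples were 2 immunoprecipitated libraries and 2 input libraries from each age. The deposited results are 4 peak lists, 1 for each age and strand, so the replicates of an age are combined. These lists hold no value per replicate, so no difference between ages was tested, and the intervals below cover counting error only. The depth of the libraries is not given in the files. The genome background recovered from the peaks was 0.824 reads per position in young and 0.689 in aged, a ratio of 1.20. Reads are not molecules, because no molecular identifier is described. The fold, the −log10 p and the −log10 q of each peak are the authors' own values. They serve here to describe peaks and to set the lists of the 2 ages side by side at the same cut-offs.

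The first comparison asked how many R-loop peaks each age had. Young cells had 24009 peaks, 11951 on the forward and 12058 on the reverse strand. Aged cells had 16198 peaks, 8088 on the forward and 8110 on the reverse strand. The young lists were thus 1.48 times as long and covered 5796 kb against 4119 kb in aged. A fold of at least 5 kept the order, with 7868 young and 6089 aged peaks, and a −log10 q of at least 5 turned it, with 3166 and 3505. It also turned at the higher thresholds, which were chosen after the data were seen. Peaks with at least 20 reads at the summit numbered 557 in young and 944 in aged, a ratio of aged to young of 1.69. At 100 reads or more there were 147 young and 274 aged peaks. A fold of at least 10 was reached by 212 young and 568 aged peaks, and a −log10 q of at least 10 by 559 and 1306. Most peaks in both ages were small. The median summit held 8 reads in each of the 4 lists, and 81.8% of young and 77.0% of aged peaks had 10 reads or fewer. The 4 median widths lay between 215 and 221 bp.

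The strongest peaks inside genes lay mostly in genes that carried a peak in both ages. The fold given for a gene is that of its strongest peak in each age, and these need not lie at the same site or on the same strand. The fold also depends on the local background, so a higher fold need not mean more reads. Camk1d, which encodes a calcium/calmodulin-dependent kinase, held the highest young fold, 146, on the reverse strand in its interior (chromosome 2, 5379040 to 5379446, GRCm38). In aged cells the Camk1d peak had a fold of 68.8 and started at the same base. Its summit reads were close, 364 in young and 343 in aged, and its local background was higher in aged. The highest aged fold lay in Ttc21b, a gene of intraflagellar transport (chromosome 2, 66189206 to 66189479), with 139 and 1248 summit reads. Ttc21b had a fold of 37.0 and 299 reads in young. Peaks with folds above 40 in both ages also lay at Lars2, the mitochondrial leucyl-tRNA synthetase gene (51.3 young, 64.7 aged), and at Tmem267 (44.1 young, 63.4 aged). Gphn, which encodes the scaffold protein gephyrin, had 32.5 in young and 36.0 in aged. The peak in the polycomb cofactor gene Jarid2 had 29 in young and 24.5 in aged, and the LIM-domain gene Lpp had 23.7 and 59.6. Gabpb1, an ETS-complex subunit gene, had 20.4 in young and 69.2 in aged. Ubtf, which encodes a transcription factor of ribosomal RNA genes, had 17.5 and 55.1. The fragile-site gene Wwox had 19.4 in young and 53.3 in aged, and Ppp1r9a had 20.3 and 82.9. In these genes the strongest young peak lay on the reverse strand and the strongest aged peak on the forward strand. Both genes held peaks on both strands in each age. At Ppp1r9a young had more summit reads, 649 against 579, over a local background of 31 against 6. Lars2 (307 young, 290 aged), Tmem267 (260, 223) and Gphn (73, 61) also had more young reads but a higher aged fold. At Ttc21b, Lpp, Gabpb1, Ubtf and Wwox the aged peak had more reads as well as the higher fold. These reads are not scaled for depth. Sfi1, a centrin-binding protein gene, held 25 young and 29 aged peaks, with top folds of 32.2 and 21.5. The young list of the 10 strongest genes further held Pik3cb, a phosphoinositide kinase gene, with a fold of 35.6, and the homeobox gene Pknox1 with 20.8. In aged Pik3cb had only a peak of fold 4.50 and 8 reads, at another site, and Pknox1 had none. The aged list of 10 held Ror2, a receptor tyrosine kinase gene, with 54.0. Its only young peak had a fold of 4.38 and 7 reads, at another site. Among the 100 strongest peaks of each age, 86 young and 86 aged peaks overlapped a peak of the other age on the same strand. Many of these sites had raised control signal. No filter for repeated sequence was applied here, and the treatment of multiply mapping reads is not given. Such reads were not tested as a source of these peaks. The local background was more than 2 times the genome level at 52 of the 100 young and 65 of the 100 aged peaks, and 57 and 88 of them also overlapped a peak of the opposite strand.

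The second comparison asked which R-loop regions were found in both ages. Of the young peaks 1751, or 7.29% (95% Wilson interval 6.97 to 7.63), overlapped an aged peak on the same strand by at least 1 bp. Of the aged peaks 1739, or 10.7% (10.3 to 11.2), overlapped a young peak. Random placement on the same chromosomes gave 0.360% and 0.502%, so the overlap lay 20.3 and 21.4 times above random placement. The remaining 22258 young and 14459 aged peaks were found in 1 age only. The share found again was higher for peaks with more reads. It was 3.22% (2.84 to 3.67) for young peaks of 5 to 7 reads, 9.16% for 10 to 14, 43.6% (39.8 to 47.5) for 15 to 29, and 87.2% (83.2 to 90.3) for 30 reads or more. For aged peaks the corresponding shares were 4.96% (4.48 to 5.47), 12.2%, 31.8% (29.2 to 34.6) and 61.9% (57.8 to 65.8). The number of shared peaks was nearly the same counted from either age, so the higher aged share follows from the shorter aged lists, and with the strongest 8088 peaks of each list the shares were 9.04% in young and 8.98% in aged. At a −log10 q of at least 5 in both lists the shares were 18.9% and 16.9%.

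Peaks that lay on both strands were more frequent in the aged lists. In aged cells 1496 peaks, 9.24% (8.80 to 9.69), overlapped a peak of the other strand, against 390 or 1.62% (1.47 to 1.79) in young. Random placement gave 0.602% and 0.343%. Within peaks of 10 to 14 reads the shares were 12.3% (11.2 to 13.5) in aged and 1.12% (0.885 to 1.41) in young, and within peaks of 15 to 29 reads they were 38.0% (35.2 to 40.9) and 15.7% (13.1 to 18.8). With the lists of both strands cut to peaks over the plain genome background, the shares were 1.98% in aged and 0.371% in young. Cutting both lists lowers such a share by itself. Peaks of few reads also lay more often at that background, and at 5 to 7 reads only 1.79% of aged and 0.201% of young peaks met the other strand. The lower shares therefore do not tie peaks on both strands to raised control signal.

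**Figure D1:**
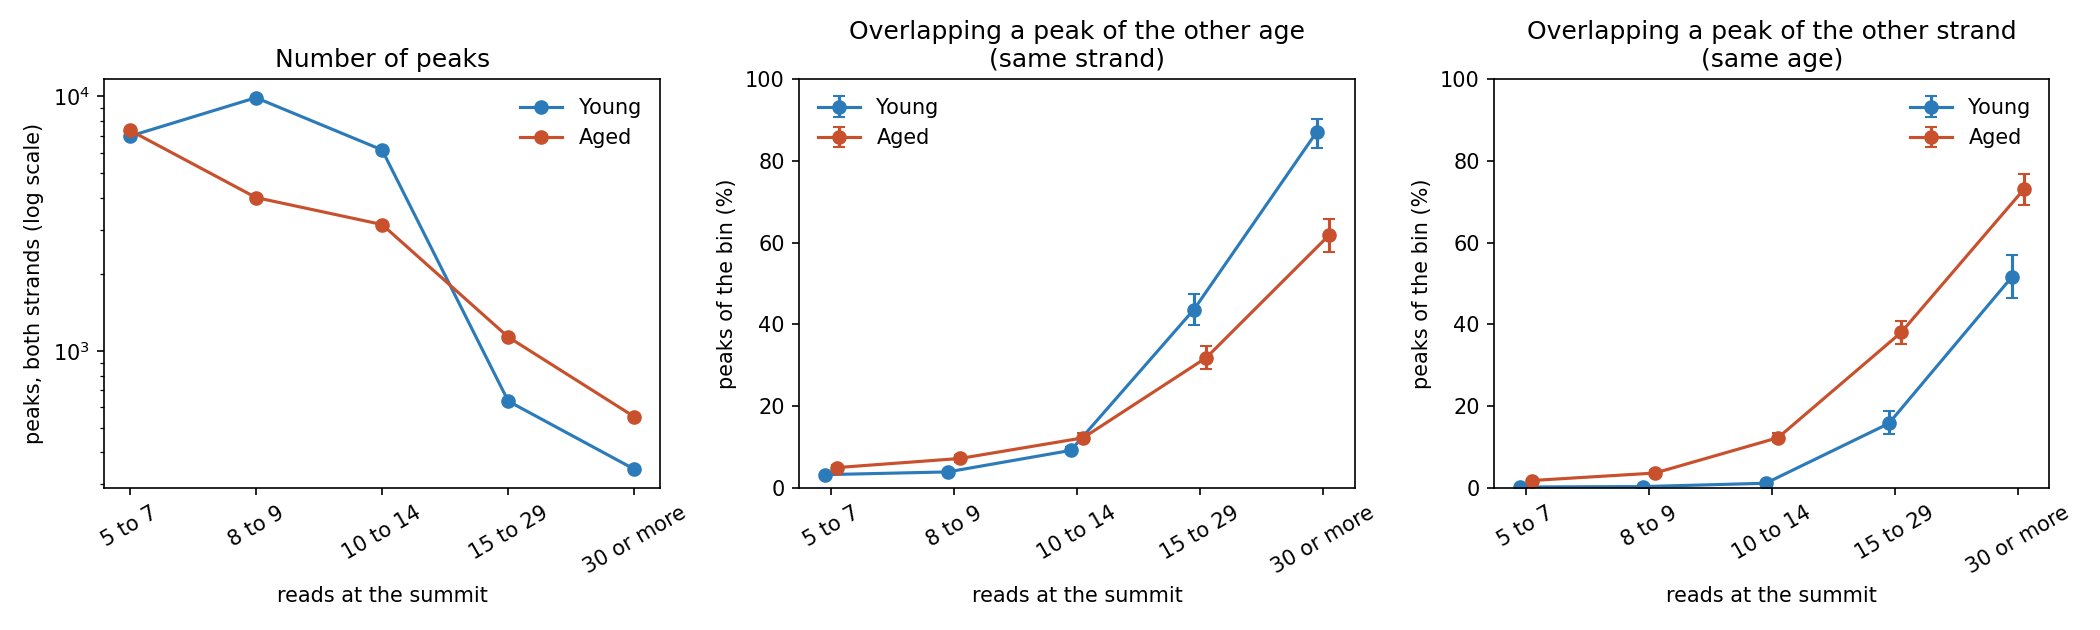
Number of peaks on a log axis (left), share overlapping the other age on the same strand (middle) and share overlapping the other strand of the same age (right), by reads at the summit; blue is young, red is aged, and bars are 95% Wilson intervals. Young cells had more peaks of 8 to 14 reads and aged cells more of 15 or more, and the share found in the other age reached 87.2% of young and 61.9% of aged peaks at 30 reads or more.

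The third comparison asked where in the genome the peaks lay. Aged peaks were found more often near the ends of genes than random positions were, while the young list as a whole was not. In aged cells 1001 of 16028 summits on the main chromosomes, 6.25% (5.88 to 6.63), lay within 1 kb of either end of a gene, against 4.79% (4.46 to 5.13) for random positions. In young cells 1108 of 23833, 4.65% (4.39 to 4.92), lay there, against 4.73% (4.49 to 4.99). The ratio to random was 1.304 in aged and 0.983 in young. Aged peaks of few reads lay above random positions too, with 5.70% (5.19 to 6.25) in aged and 4.60% (4.14 to 5.12) in young at 5 to 7 reads, and 5.62% (4.95 to 6.38) and 4.65% (4.25 to 5.08) at 8 to 9 reads. The gap was widest among peaks of 10 to 14 reads, with 7.29% (6.43 to 8.25) in aged and 4.34% (3.85 to 4.87) in young. At 15 to 29 reads the shares were 8.79% (7.27 to 10.6) in aged and 6.61% (4.89 to 8.88) in young, and at 30 reads or more 7.31% (5.20 to 10.2) and 8.84% (5.91 to 13.01), with overlapping intervals in both classes. Young peaks of 30 reads or more thus lay above random positions too. Gene interiors held 43.2% of young and 43.9% of aged summits, and random positions 43.7% and 43.9%. The gene table gives no gene strand, so the start of a gene could not be told from its end.

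**Figure D2:**
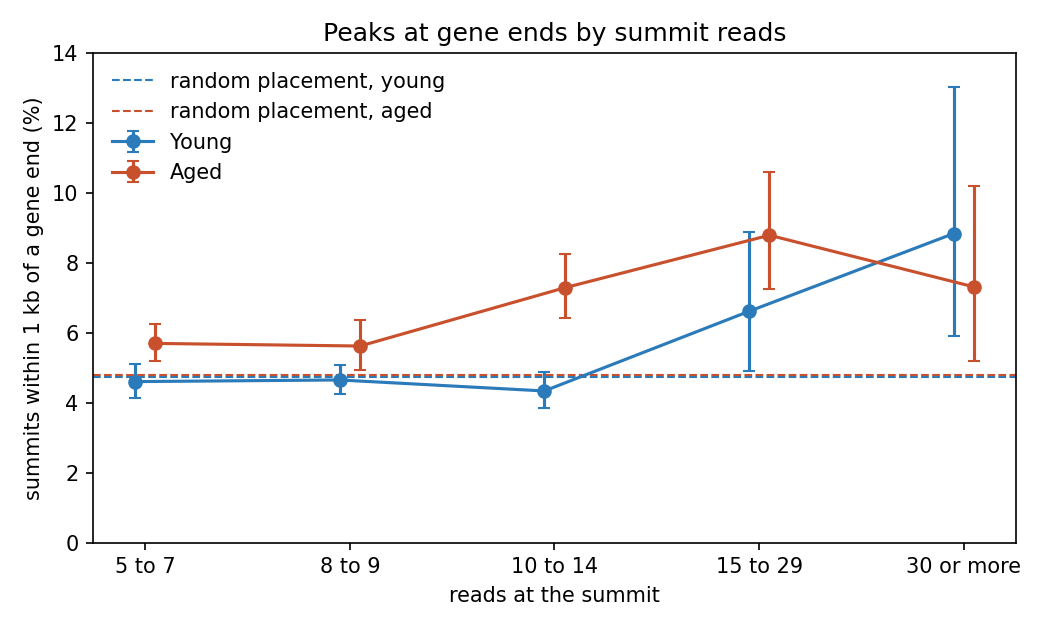
Share of peak summits within 1 kb of either end of a gene (y axis, percent) by reads at the summit (x axis), for young (blue) and aged (red) peaks with 95% Wilson intervals; dashed lines are random placement. The aged share at 10 to 14 reads was 7.29% against 4.34% in young, and random placement gave 4.73% for young and 4.79% for aged.

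The fourth comparison asked which genes carried a peak. Of 34614 protein-coding and lncRNA genes, extended by 1 kb at either end, 6867 held a young and 5561 an aged peak. Random placement of the same peaks gave 7284 (7168 to 7391) and 5530 (5430 to 5641). Both ages had a peak in 2726 genes, 4141 genes had a young peak only and 2835 an aged peak only. Random placement gave 2596 (2529 to 2663) genes with both, 4688 (4571 to 4800) with young only and 2934 (2846 to 3014) with aged only. The counts of genes with a peak in 1 age only thus lay below random placement. The strongest aged-only gene was Pxylp1, a xylose phosphatase gene of glycosaminoglycan synthesis, with a fold of 51.4 and 179 reads on chromosome 9 (96853022 to 96853202). It was followed by Patl1, an mRNA decapping factor gene (25.5), Abhd6, a monoacylglycerol lipase gene (24.7), Treml2 (20.7) and the SUMO gene Sumo3 (19). Gas5, a noncoding host of small nucleolar RNAs, had 18 with 35 reads (chromosome 1, 161035746 to 161036403). Elf2 (16.6), BC016579 (16.5), Col18a1 (16.0) and Sos2 (14.9) completed the 10. The young-only genes had lower folds. After Pknox1 the highest were Zfp991 (14.1), Slc14a2, a urea transporter gene (10.6), Gpr141 (10.4) and Ccdc190 (10.4). Zc3h3 (9.88), Prkaa1, which encodes a catalytic subunit of the energy sensor AMPK (9.33), Frmd3 (9.31), Rtl9 (8.99) and Speer4c (8.78) followed. A peak in 1 age only is not shown to differ between ages, since each age has 1 combined list and no test was run. Most peaks of few reads were not found again. Some of the genes named had many reads over a raised local background, as Sos2 (334 reads over 21.5) and Slc14a2 (190 over 17). Others lay at the genome level, as Patl1 (42 reads over 0.689).

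Ribosomal protein genes stood out in aged cells. Of the 84 genes of this list, 24 had an aged peak and 6 a young peak, where random lists matched on gene length and biotype had 4.47 (1 to 9) and 3.92 (1 to 8). The aged count lay above all 10000 random lists, and the young count at the 85.7th percentile. The 21 genes with an aged peak only included Rps12 (fold 11.2, 18 reads, chromosome 10, 23784630 to 23784890), Rpl38 (10.7), Rps29 (10.7) and Rplp2 (9.47). Rps16 had a fold of 9.47 in aged and, at another site, of 7.13 in young, and the 3 genes with a young peak only were Rps15a, Rps27a and Rpl8. Within 1 kb of a gene end 20 of these genes had a summit in aged (random 3.08, 0 to 7) and 4 in young (2.64, 0 to 6). These genes are short, so this does not place the peaks at the ends rather than in the genes as a whole. With the same number of the strongest peaks from each list the counts were 24 in aged and 4 in young. This cut shortens the young lists and leaves the aged lists nearly whole. At a −log10 q of at least 5 they were 11 and 2.

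Long or structural noncoding RNAs lay above random lists in 4 of 5 settings in aged and in 3 of 5 in young, the main setting included. The cut to the strongest 8088 peaks keeps the aged lists, of 8088 and 8110 peaks, nearly whole. For aged it therefore all but repeats the main setting. Of 14 genes found in the table, 6 had an aged peak (random 1.14, 0 to 3), and 4 had one at a −log10 q of at least 5 (0.28, 0 to 2). The 5 with a young peak (1.57, 0 to 4) also lay above random lists, but not with the strongest 8088 peaks of each list (2, random 0 to 3) or at a −log10 q of at least 5 (1, random 0 to 1). At gene ends only the ages changed places, with 2 in aged (random 0 to 2) and 4 in young (random 0 to 2). Malat1, an abundant nuclear RNA of nuclear speckles, had a reverse-strand peak of fold 29.6 and 49 reads in aged (chromosome 19, 5800823 to 5802466) and of 6.57 and 11 reads in young (5801070 to 5801400). Neat1, the scaffold of paraspeckles, had 9.60 with 23 reads in aged and 4 with 9 reads in young. Xist, the RNA of X inactivation, and Pvt1 had peaks in both ages. Gas5 and Snhg1 (8.29) had an aged peak only, and Tug1 (4.39) a young peak only.

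Among genes of stem cell identity, 14 of 30 had an aged peak (random 8.99, 5 to 13) and 11 a young peak (10.4, 7 to 14). Peaks in both ages lay in Slamf1, Mecom, Tek, Tal1, Kit, Meis1, Angpt1, Runx1 and Erg. The angiopoietin receptor gene Tek had the strongest, with a fold of 7.50 on the forward strand in young and 10.5 on the reverse strand in aged. Both peaks covered the same site, and each age had 1 Tek peak on either strand. The young peak had more summit reads, 29 against 19, over a higher local background. The homeobox gene Meis1 had folds of 4.93 in young and 9.47 in aged. The leukaemia-associated factor genes Tal1 and Runx1 had 6.03 and 3.73 in young and 7.70 and 7.69 in aged. In Meis1, Tal1 and Runx1 the peaks of the 2 ages lay at different sites. Lmo2, Txnip, Fgd5, Fli1 and Hoxb4 had an aged peak only, with folds of 6 at Txnip and 5.77 at Fli1. Prdm16 (6.04) and Mllt3 (6.03) had a young peak only. Of 32 genes often described as higher in aged stem cells, 15 had an aged peak (random 10.1, 6 to 14) and 12 a young peak (11.9, 8 to 16). The NAD-consuming enzyme gene Cd38 had 9.50 in aged and, at another site, 4.30 in young. The receptor phosphatase gene Ptprk (7.68 young, 5.92 aged) and the adaptor gene Fyb (7.13 young, 4.74 aged) had peaks in both. Selp (5.92), Jam2 (6.23), Runx1t1, Cyp26b1 and Vwf had an aged peak only, and Jun (6.03) and Zbtb16 (6.57) a young peak only. Both lists lay just above their random range in aged and within it at a −log10 q of at least 5 (6, random 0 to 6, and 2, random 0 to 6) and at gene ends only (3, random 0 to 3, and 2, random 0 to 4). Without peaks that had an other-strand peak within 1 kb, the stem cell identity genes fell within random too (12, random 5 to 13). The genes described as higher in aged cells stayed above in that setting (15, random 6 to 14). Marker genes of erythroid cells (4 of 13, random 1.20, 0 to 3) and of megakaryocytes (4 of 9, 1.41, 0 to 3) also lay above random in aged and had 1 gene each in young. Both fell within random at a −log10 q of at least 5 (1 and 2, random 0 to 2 for each) and at gene ends only (0 and 1, random 0 to 2 for each). Without peaks that had an other-strand peak within 1 kb both stayed above (4, random 0 to 3 for each). Erythroid genes with an aged peak were Car2 (7.35), Car1 (5.33), Slc4a1 (4.74) and Tfrc (4.73), and megakaryocyte genes were Cd9 (10.1), Gp1ba (7.95), Vwf (4.73) and Rap1b (3.60). Myeloid markers had 2 of 12 in aged, Cebpe (6.51) and Mpo (5.25), and none in young. T and NK markers had 3 of 10 in aged, Ncr1 (7.10), Gata3 (4.14) and Tcf7 (3.5), and none in young. The B-cell factor gene Ebf1 was the only one of 10 B lymphoid markers with a peak (4.50 young, 4.74 aged). Of 8 stroma and endothelium genes, Lepr had peaks in both ages (6.03 young, 4.74 aged), and Col1a1 (5.38) and Col1a2 (4.39) in young only.

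Genes of mRNA export, the process named in the series title, held peaks at the frequency of random lists. Of 39 genes, 11 had a young peak (random 8.13, 4 to 13) and 9 an aged peak (6.83, 3 to 11). Only Thoc1, of the THO complex that couples transcription to export, had a peak in both ages (6.59 young, 4.74 aged). The splicing and export factor genes Srsf7 (8.92) and Srsf3 (5.92) and the export receptor gene Nxf1 (5.92) had an aged peak only, as had Tpr, Gle1, Alyref, Nup153 and Thoc2. Nupl2 (5.49) led the 10 genes with a young peak only. R-loop resolving factors had 8 of 25 in young (8.17, 4 to 12) and 10 in aged (6.59, 3 to 11). The helicase gene Dhx9 had 4 in young and 5.22 in aged. A young peak only was found in 5 of these genes (random 4.96, 1 to 9), among them Fancm (6.67), Aqr (5.49) and Xrn2 (5). An aged peak only was found in 7 (random 3.36, 0 to 7), Bard1, Brca2, Fancd2, Ddx21, Ddx5, Rnaseh2b and Top3b. DNA damage response genes had 5 of 26 in young (5.95, 2 to 10) and 4 in aged (4.89, 2 to 9), with Rpa2 at 7.13 in young and Xrcc5 at 6.51 in aged. Innate immune genes had 4 and 5 of 24, among them Ifit1 (4.49 young, 5.33 aged). Immediate-early genes had 2 of 24 in each age. Fosl2 reached 11.2 in aged only, Jun had a peak in young only, and Klf6 had 4.18 in young and 5.92 in aged. Imprinted genes had 5 of 19 in young (5.34, 2 to 9) and 4 in aged (4.21, 1 to 8), with Kcnq1ot1 at 8.28 in aged only and Snrpn at 6.57 and 7.62. Histone genes had none of 67 in young and 2 in aged, H1f2 (8.29) and H4c6 (4.74). All 16 very long fragile-site genes had a peak in both ages (random 12.8, 9 to 16, young; 11.04, 7 to 14, aged). At a −log10 q of at least 5, 13 had a young and 14 an aged peak, against 3.5 and 3.4 (1 to 7 for each). The matching by length decile falls short for these genes, whose median length was 1593 kb against 185 kb for the genes the random lists were drawn from. Per Mb they held 10.4 young (95% Poisson interval 9.24 to 11.8) and 6.54 aged peaks (5.60 to 7.60), against 9.18 and 6.26 over the autosomes, and at a −log10 q of at least 5 they held 1.07 (0.712 to 1.55) and 1.38 (0.965 to 1.91), against 1.16 and 1.31. After Wwox the strongest aged peaks there were in Auts2 (14.5), Ctnna3 (12.5) and Cntnap2 (11.2).

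In all, 7 of 18 lists lay above the central 95% of random lists in aged and 1 in young, and none lay below. Chance alone gives an expected number of at most 1.8 of the 36 comparisons outside on either side. Most of the aged excess did not hold in stricter settings: 3 aged and 1 young lists lay above at a −log10 q of at least 5, and 1 of each at gene ends only. Only the ribosomal protein genes lay above in aged in every setting tried. The lists share genes, and the percentiles describe these peak lists and do not test age.

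**Figure D3:**
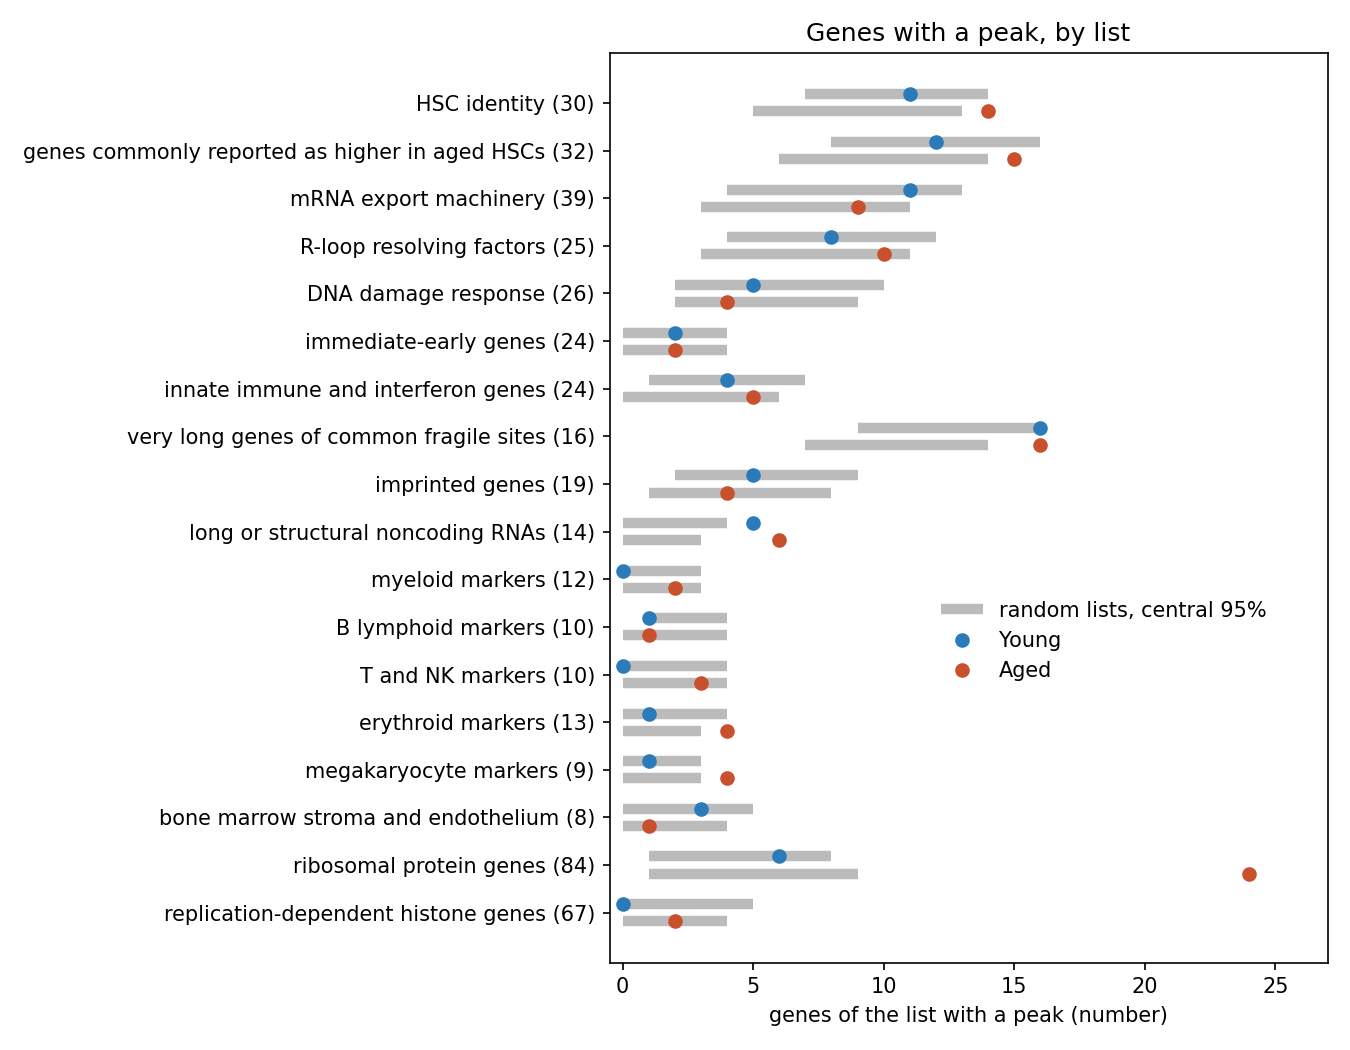
Number of genes with a peak (x axis) in each of 18 gene lists (y axis, list size in parentheses), for young (blue) and aged (red) peaks; grey bars are the central 95% of 10000 random lists of the same size, gene length and biotype. Ribosomal protein genes with an aged peak numbered 24, against 1 to 9 in random lists.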

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

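The tests of the neighbouring genes, of the pseudogenes, of thinned young peaks and of strong peaks at the genome background were fixed before their results were seen; the other tests of this part, and the use of recovered reads, were chosen after the result was seen.

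Peaks on the mitochondrial genome and on unplaced sequence entered no location or gene comparison and are given as values. The highest fold on the mitochondrial forward strand was 99.9 with 1347 reads in aged and 26.2 with 496 reads in young. On the reverse strand it was 11.7 in aged and 2.43 in young. A single unplaced scaffold of GRCm38 held 87 peaks in young and 119 in aged, over both strands.

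Young lists were longer, yet aged lists held more strong peaks. The intervals here count the peaks of each strand apart and are too narrow, since 1 site can count on both strands. At 30 reads or more 73.1% of aged and 51.6% of young peaks met the other strand. Each strand alone kept the order at 20 reads, with 290 young and 492 aged forward peaks and 267 and 452 reverse peaks. Greater depth in aged is argued against for this excess: strong peaks numbered 1.69 times as many in aged (95% exact interval 1.52 to 1.89), while the aged background was 0.837 of the young. This takes the background as the depth used by the caller, which fits the whole reads found at 100% of peaks and smallest peak widths of 182 bp in young and 181 bp in aged; the depth before the unexplained normalization is unknown. Raised control signal is argued against as the whole source of that excess, because peaks of at least 20 reads over the plain genome background numbered 122 in aged and 35 in young, a ratio of 3.49 (2.38 to 5.23); the other strong peaks lie over raised background, where it stays open. For the longer young lists depth cannot be told apart from age: after thinning young summits to the aged background, 21207 peaks (SD 41.8 over 100 thinnings) still passed the lowest aged −log10 p against 16198 aged peaks. That prediction had been written as deciding against depth, but it reads the summit alone and not the width a peak needs, and the median young widths of 215 and 216 bp lie close to the smallest, 182 bp. Age itself, the unstated normalization, amplified copies of single fragments and spread between the 2 replicates of an age stay open, as untested.

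Ribosomal protein genes carried a peak more often in aged than matched random lists. Stronger aged peaks are argued against as the whole source: with 12854 peaks of each age drawn to match in summit reads, a mean of 20.4 of 84 genes over 1000 draws had an aged peak (24.3%, Wilson 16.4 to 34.5) and 3.498 a young one (4.16%, 1.54 to 10.8), and with 8401 peaks matched on −log10 p the means were 16.4 (19.6%, 12.5 to 29.3) and 1.32 (1.57%, 0.334 to 7.04). A property of their neighbourhood is argued against, since 16 of 83 nearest other protein-coding genes had an aged peak (random 16.9, 11 to 23.0), 0.945 times random against 5.36 times for the list. Reads shared with processed pseudogenes stay open. Of 310 ribosomal protein pseudogenes 1.61% (0.691 to 3.72) had an aged peak, as had 2.86% of 9634 other pseudogenes. That prediction had been written as deciding against shared reads. It cannot decide, because the treatment of multiply mapping reads is not given. The ribosomal protein pseudogenes were also picked by symbol alone. A difference in R-loops with age at these highly transcribed genes, carry-over of their abundant RNA into the aged libraries, base composition, and a different cell makeup stay open as untested. Erythroid and megakaryocyte markers lay just above random in aged, also without peaks that had an other-strand peak within 1 kb (4, random 0 to 3 for each). Both lay within random at a −log10 q of at least 5 or at gene ends only, where few genes are counted. The lineage-negative gate of the sort would remove most mature cells, but the cell makeup was not measured.

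Few peaks were found in both ages. Chance placement of every weak peak is argued against: young peaks under 8 reads were found in aged in 3.22% (2.84 to 3.67), against 0.155% for the same peaks at random. A mixture in which most weak peaks lie at chance positions would give such a share too, so chance stays open for most of them. If the same sites gave Poisson reads scaled to the aged background, 94.5% of young peaks of 15 to 29 reads would be found again and 43.6% (39.8 to 47.5) were; for 16866 young peaks under 10 reads these were 68.7% and 3.62% (3.35 to 3.91). A peak picked for its height overstates its site in both classes, so too few reads cannot be told apart from absence in either. Amplified copies of single fragments, spread between replicates beyond Poisson, and age stay open, since 1 combined list per age tests none of them.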

How the results depend on the processing

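No paired analysis was possible with the deposited lists because each age has 1 combined peak list per strand, so no fit by replicate exists and leaving out a replicate was impossible. The planned settings for gene strand and base composition were not run. Settings at a −log10 q or fold of at least 10, at 20 reads, at the genome background or without peaks of the other strand within 1 kb were chosen after seeing the data. Counts fall under stricter thresholds by construction; for the other shifts the cause was not tested. Autosomes and merging left peak numbers within 1.5 times, and the strongest 8088 peaks per list left the numbers of genes with a young, an aged or both peaks within 1.5 times. Most peaks hold 10 reads or fewer, which limits every result that counts all peaks. Whether depth causes the shifts between these settings was not tested.

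The log2 ratio of young to aged peak number was 0.57 and turned to −0.15 at a −log10 q of at least 5, −1.22 at 10, −1.42 at a fold of at least 10 and −0.76 at 20 reads. It was 0.37 at a fold of at least 5, 0.51 at the genome background and 0.68 without other-strand peaks. In the order young forward, young reverse, aged forward and aged reverse, peaks numbered 1580, 1586, 1765 and 1740 at a −log10 q of at least 5; 3877, 3991, 3046 and 3043 at a fold of at least 5; 286, 273, 644 and 662 at a −log10 q of at least 10; 108, 104, 286 and 282 at a fold of at least 10; 290, 267, 492 and 452 at 20 reads; 6181, 6226, 4330 and 4354 at the genome background.

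The young and aged shares found in the other age were 6.36% and 9.43% with 50% reciprocal overlap, 8.40% and 12.4% with peaks extended by 1 kb, 18.9% and 16.9% at a −log10 q of at least 5, 24.6% and 26.4% with that threshold in the list asked about only, 9.04% and 8.98% with the strongest 8088, 6.86% and 10.1% on autosomes, 4.84% and 7.60% at the genome background, and for aged 11.8% with either strand. Random placement by shifts of 10 to 100 kb gave 0.284% and 0.415%. Other-strand shares were 1.37% and 8.21% with reciprocal overlap, 7.80% and 24.7% at a −log10 q of at least 5, and 0.371% and 1.98% at the genome background. At the q threshold and at the genome background the lists of both strands were cut. Gene-end shares were 2.26% and 3.19% with 500 bp windows, 12.0% and 14.7% with 3 kb, 3.01% and 4.49% for protein-coding genes, and 5.04% and 7.85% at a −log10 q of at least 5. The aged ratio to random was 1.27, 1.17 and 1.47 for the first 3, and the young ratio 0.911, 0.964 and 0.998. Gene-interior shares were 44.7% and 45.7%, 38.9% and 39.0%, and 37.9% and 38.5% in those settings, and 41.7% for young at a −log10 q of at least 5.

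Genes with a young, an aged and both peaks numbered 1201, 1068 and 158 at gene ends only and 1252, 1476 and 348 at a −log10 q of at least 5. Of 144 gene-list counts under alternatives, 83 stayed within 1.5 times and 61 moved. Lists above random numbered 7 aged and 1 young in the main setting and with the strongest 8088, 6 and 1 without other-strand peaks, 3 and 1 at a −log10 q of at least 5, and 1 and 1 at gene ends only; the young list was the noncoding RNAs, or the fragile-site genes with the strongest 8088 and at a −log10 q of at least 5. Given as young then aged, at gene ends only, stem cell identity had 1 and 3, aged-cell genes 1 and 2, mRNA export 1 and 4, R-loop factors 1 and 3, DNA damage 0 and 0, immediate-early 0 and 1, innate immune 1 and 1, fragile-site 1 and 0, imprinted 0 and 1, myeloid 0 and 1, B lymphoid 0 and 0, T and NK 0 and 1, erythroid 0 and 0, and megakaryocyte 0 and 1; noncoding RNAs had 2 and stroma 0 in aged. At a −log10 q of at least 5, stem cell identity had 2 and 6, aged-cell genes 3 and 2, mRNA export 1 and 1, R-loop factors 1 and 0, DNA damage 2 and 1, immediate-early 0 and 1, innate immune 0 and 0, imprinted 1 and 2, myeloid 0 and 1, B lymphoid 0 and 0, T and NK 0 and 1, erythroid 0 and 1, megakaryocyte 0 and 2, stroma 0 and 0, histone 0 and 1, and ribosomal protein genes 2 and 11; noncoding RNAs had 1 in young. With the strongest 8088, young immediate-early genes had 1, imprinted genes 2 and noncoding RNAs 2.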

Other observations

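The X chromosome held 7.29% of young peaks (95% Wilson interval 6.97 to 7.62) and 5.90% of aged peaks (5.55 to 6.28). Per Mb this was 10.4 young peaks on X against 9.18 on the autosomes, and 5.70 aged peaks on X against 6.26. The Y chromosome held 27 young and 48 aged peaks. The labels do not give the sex of the donors, so sex was not matched or compared between the ages here.

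Peaks also met the opposite strand of the other age. Of young peaks 2.10% (1.93 to 2.29) overlapped an aged peak on the opposite strand, and 3.11% of aged peaks (2.85 to 3.38) overlapped a young peak there, 6.03 and 6.20 times random placement. Peaks found in both ages lay at gene ends in 6.23% of young (5.17 to 7.51) and 6.38% of aged cases (5.30 to 7.66). Peaks found in 1 age only lay there in 4.53% of young (4.26 to 4.81) and 6.23% of aged cases (5.85 to 6.64). Shared peaks of the 2 ages are largely the same positions, and reads were not matched between shared and other peaks, so these shares do not compare the ages.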
